A study of Mus musculus with 10 samples.

How the data were processed

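The series holds 10 samples of mouse retina, and 8 of them have a peak list: ATAC-seq from 2 control and 2 Casz1 cKO libraries, and ChIP-seq for H3K27ac and H3K27me3 from 1 control and 1 cKO library each. The 2 input chromatin samples were not analysed here. Groups and replicate numbers were taken from the sample titles. Per the labels' protocols, ATAC libraries were made from 50000 sorted cells with 12.5 µl of Tn5 for 30 minutes at 37 °C, and ChIP tissue was fixed in 1% formaldehyde for 10 minutes and sheared to about 300 bp.

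The deposited files give each peak's chromosome, start, end and name. The score column is 0 throughout and the strand column is the same throughout, so the lists hold no height, fold enrichment, p-value, q-value, summit or read count. Bowtie2, deepTools, MACS2 and the build mm10 are named in the submitters' processing notes, without versions or parameters; the peak threshold, duplicate removal, any shift of reads for the Tn5 cut, and the use of input are not given in the sources used here. Per the file headers, here the names given to peaks, each list comes from one set of aligned reads, so peaks were taken as called per library and not on pooled samples, and mm10 appears in the names of 3 ATAC lists. Because the depth of each library is unknown, a longer list can come from deeper sequencing, and no precision per peak can be given. Peak calling can break the broad domains of H3K27me3 into pieces, and whether a narrow or broad mode was used is not given. Covered bases were therefore used beside presence for the histone marks.

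Peaks on chromosomes 1 to 19 and X were kept. Peaks elsewhere made up from 0.0647% to 0.372% of a list. ATAC lists were merged into union regions (1 bp minimum overlap), and a region counted as genotype-specific when called in both libraries of one genotype and in neither of the other. Jaccard indices are shared bases over bases covered by either list. For the 3 ways to split 4 lists into pairs, the difference of mean Jaccard within and between pairs gave an exact permutation test. Shares of unshared peaks carry exact Clopper-Pearson 95% intervals, which cover counting error only. Per the labels' protocols, the ATAC experiments were run on separate days; for the histone marks there is 1 library per group and no test.

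Gene positions came from a RefSeq table of GRCm38.p6, the assembly called mm10, with 21631 protein-coding genes. It gives start and end without strand or transcripts, so the planned 5' end was replaced by both annotated ends. A promoter peak here means a peak within 1 kb of either end, which may not be the promoter. Covered bases were summed over the 10 kb centred on each end, overlapping windows counted once. Exons, introns and untranslated regions were therefore not assigned, and regions are placed only as inside or outside a gene. The planned search for sequence motifs needs a genome sequence and was not run. Stricter peak thresholds and equal list lengths by the caller's p-value, planned as alternatives, were not run for want of these values.

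Before the data were examined, 25 gene lists with 510 entries were fixed, of which 509 matched, 4 by an older symbol: rod photoreceptor, cone photoreceptor, photoreceptor regulator, bipolar, Müller glia, retinal progenitor, neurogenic progenitor, ganglion, amacrine, horizontal, early-born fate, temporal patterning, NuRD, Polycomb, Hox, non-neural developmental regulator, cell cycle, housekeeping, pigment epithelium, vascular, microglia and macrophage, astrocyte, lens and cornea, erythroid, and liver and muscle genes. For each list and mark, the mean cKO minus control change was set among 10000 random gene lists of the same size, matched by deciles of the mean coverage of both libraries. This percentile describes these libraries and is not a test. Lists for dorsal retina, ventral retina, p53 targets and the interferon response were added after the data were seen.

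Genes were named by a rule fixed in advance: Casz1; the 10 ATAC regions per direction with the highest lower rank percentile across the pair of lists; the 10 genes per mark and direction with the largest change of covered bases; members of the fixed lists whose promoter gained or lost a peak or with a genotype-specific ATAC region nearest within 50 kb, up to 4 per list and direction; and the Hox clusters. The rule ranked peaks by the caller's signal value. As the lists hold none, peak width was used in its place. Other list members are named for the size of their change, seen first. Some genes that the rule or these choices took are not reported here.

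For the pairing of replicate numbers, the covered bases of each union region, on a log scale, were centred on their group mean. Libraries with the same number had deviations that correlated at -0.274. The crossed numbers then give 0.274 by construction, which is not a separate result. The labelled numbers were not used as a block in the reported values.

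Alternatives were autosomes only, at least 50% of a region covered, merging of peaks within 500 bp, leaving out each ATAC library, blocks of replicate numbers, promoters of 2.5 kb, windows of 4 kb, random lists without matching and a limit of 10 kb to the nearest gene. Added after the data were seen were equal list length by peak width, peaks of at least 300 bp, gene bodies with 5 kb either side, crossed replicate numbers, and, for the lists, autosomes only, 4 kb windows and removal of shared members. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

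The interval functions were checked against bedtools 2.31.1 on all 28 pairs of lists, with 0 differences, and both found 118715 union regions. The list percentiles were tested on simulated data, with changes redrawn within coverage deciles over 21631 genes. Random lists of 20 genes fell outside the middle 95% in 3.75% of 400 lists for H3K27ac and 6.25% for H3K27me3. A shift of 300 bp put 99% and 86% of 100 lists above the 97.5th percentile, and a shift of 500 bp put 100% of them there for both marks.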

Results

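Chromatin was profiled in neonatal mouse retina (strain C57BL/6) with and without Casz1, a zinc finger transcription factor that acts in retinal progenitors. Open chromatin was measured by ATAC-seq, in which the transposase Tn5 cuts accessible DNA, in 2 control and 2 Casz1 conditional knockout (cKO) libraries from explants of postnatal day 2 retina. The explants received a plasmid encoding GFP, with Cre for the cKO, and 50000 live GFP-positive cells per library were sorted 2 days later. Chromatin immunoprecipitation of H3K27ac, a mark of active promoters and enhancers, and of H3K27me3, the mark laid down by Polycomb repressive complex, was done on dissected retina at postnatal day 0, with 1 control and 1 cKO library per mark. The cKO tissue for these came from peripheral retina chosen by its fluorescence. Each library was represented by its list of called peaks, without read counts, so its depth is unknown and no interval for read depth is given.

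Peak numbers on chromosomes 1 to 19 and X differed most among the ATAC libraries. Control replicate 1 held 40435 ATAC peaks over 11.8 Mb and control replicate 2 held 110741 over 61.0 Mb, against 93767 over 52.7 Mb in cKO replicate 1 and 60824 over 20.004 Mb in cKO replicate 2. The H3K27ac lists held 71605 peaks (55.4 Mb) in control and 77357 (51.6 Mb) in cKO, and the H3K27me3 lists 92652 (87.4 Mb) and 89523 (84.5 Mb).

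The Casz1 locus (mm10, chromosome 4, 148804366 to 148954893) carried open chromatin and active marks in all libraries. It held 20 and 33 ATAC peaks in control replicates 1 and 2, and 30 and 33 in cKO replicates 1 and 2. H3K27ac covered 65.5% of the locus in control and 60.7% in cKO, and H3K27me3 covered 1621 bp and 1887 bp. The deleted part of the gene is not given in the sources used here, so these peaks do not check the genotype labels.

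The first comparison asked which places were open in one genotype and not in the other. A region near Cdkn1a, the gene of the cell cycle inhibitor p21, stood first among those called in both cKO lists and in neither control list. It lay on chromosome 17 at 29077958 to 29078681, 12.7 kb outside the gene and in no annotated gene, with peaks of 534 bp and 438 bp in cKO replicates 1 and 2. A second region 231 bp away was called in all 4 lists, so that merging peaks within 500 bp joins the pair and ends the genotype-only call. Next by the lower of the within-list width percentiles were regions in Fam184b (chromosome 5, 45599097 to 45599657, 532 and 534 bp), near Gm7260, near Snx13 and near Morc1, followed by regions in Myo1d, in Mid1, in Cacna2d2, in Gm21154 (nearest gene end that of Gm5799) and near Tbc1d32. On the control side the first was in Dgkb (chromosome 12, 38127346 to 38127899), a diacylglycerol kinase gene, with peaks of 267 bp and 554 bp. The others included regions in Pde4d, a phosphodiesterase gene, Pcdh17, Tbc1d30, Efl1, Lrba (nearest gene end that of Mab21l2), Gm3488 and Tpcn2 (nearest Smim38), and near Kif26a.

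Within 50 kb of a protein-coding gene end lay 201 cKO-only and 105 control-only regions. The fixed lists held 459 of 21631 such genes, so small counts near them are no sign of depletion. Of the 459 listed genes, 5 were nearest to a cKO-only region within 50 kb: Cdkn1a, the cone photoreceptor gene Kcne2 (42.5 kb), the glial transcription factor gene Nfia (9.59 kb), and Mbd2 (15.1 kb) and Chd5 (4.35 kb), which encode subunits of the NuRD nucleosome remodelling complex. Tbx20 (13.7 kb) and the pericyte receptor gene Pdgfrb (9.39 kb) were nearest to a control-only region. The NuRD list, with 2 cKO-only regions near its 15 genes, lay at the 98.7th percentile of random lists matched on their number of ATAC regions, and 1 of its 2 regions, that at Chd5, lay within 10 kb. Of the 50 combinations of 25 fixed lists and 2 directions, 1 lay above the middle 95%, where 1.25 would by chance. Within 50 kb of a gene end, no region of either kind was nearest to a member of the rod, bipolar, retinal progenitor, neurogenic progenitor, ganglion, amacrine or horizontal cell lists. These lists lay between the 26.2nd percentile (amacrine, cKO-only) and the 44.2nd (horizontal, control-only). Having no such region is thus common among matched random lists and does not set these lists apart. Beyond 50 kb, the bipolar gene Prkca was nearest to cKO-only regions on chromosome 11 (108204957 to 108205252 and 108020823 to 108021077). The progenitor gene Zic1 was nearest to a control-only region on chromosome 9 (90964183 to 90964371).

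Regions called by genotype were a small part of the whole. The 4 lists merged into 118715 regions, of which 33508 were called in all 4, 325 in both cKO lists only (0.274%) and 146 in both control lists only (0.123%). The lists paired across genotype. Control replicate 1 and cKO replicate 2 had a Jaccard index of covered bases of 0.532, and control replicate 2 and cKO replicate 1 one of 0.704, while the control lists reached 0.192 and the cKO lists 0.361. The mean within genotype was 0.276 and between genotypes 0.444 (difference -0.167; one-sided exact permutation p = 0.667 over 3 splits, where the smallest possible is 0.333). The difference was -0.0153 without control replicate 2, and 0.00716 when only libraries of the same number were compared between genotypes. Split by the labelled numbers, 26 regions were called in the replicate 1 lists only and 1214 in the replicate 2 lists only. Split by the pairs across genotype, 33256 regions were called in control replicate 2 and cKO replicate 1 only, and 204 in the other pair only. Within the pairs, control replicate 1 against cKO replicate 2 gave 1577 control-only and 20417 cKO-only regions, and control replicate 2 against cKO replicate 1 gave 24404 and 7060, so the direction of the difference turned between pairs. Among regions that differed in both pairs, 316 cKO-only and 137 control-only regions would follow from the margins, beside the 325 and 146 counted. The labels state that 2 experiments were run on separate days, without saying which libraries shared a day. The peak names carry the number 1 for control replicate 1, 3 for both control replicate 2 and cKO replicate 1, and 5 for cKO replicate 2, and what this number stands for is not given in the sources used here.

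**Figure D1:**
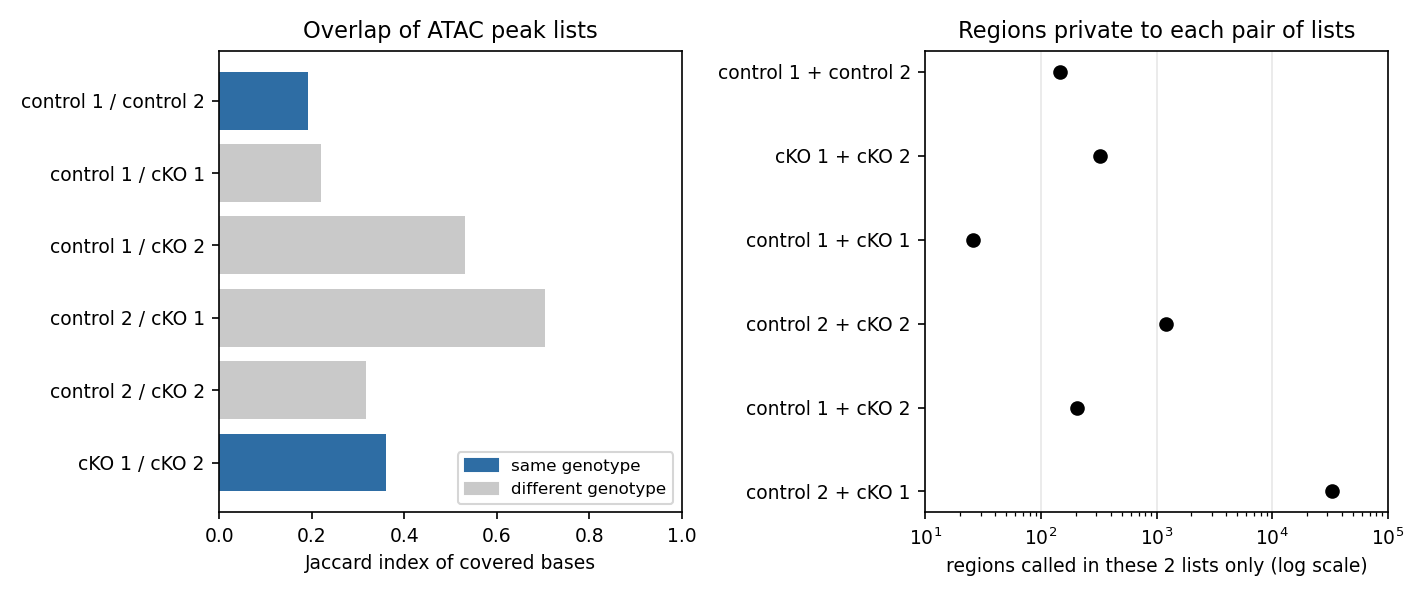
The left panel plots the Jaccard index of covered bases (0 to 1) for each pair of ATAC peak lists, in blue for lists of the same genotype and in grey for lists of different genotypes. The right panel plots, on a log scale, the regions called in the named 2 lists only, from 26 for control 1 with cKO 1 to 33256 for control 2 with cKO 1, and 146 and 325 for the genotypes.

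The genotype-specific regions were narrow and away from gene ends. The lower of the width percentiles had a median of 8.95 for cKO-only and 6.94 for control-only regions, and 8 cKO-only regions and 0 control-only regions had peaks of at least 300 bp in both lists. Of the cKO-only regions, 3.08% lay within 1 kb of a gene end, beside 2.74% of control-only regions and 32.5% of those called in all 4. Without control replicate 2, the cKO-only count was 18030; without cKO replicate 2 it was 6991; without cKO replicate 1 it was 1498. Without control replicate 1, the control-only count was 22948, and it was 415 without control replicate 2, 1282 without cKO replicate 1 and 388 without cKO replicate 2.

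The second comparison asked where H3K27ac differed in cKO retina. The gene of Dll1, a ligand of the Notch receptor, was among the 10 genes with the largest decrease in bases covered by H3K27ac peaks, counted in the 10 kb windows around the gene's 2 ends, from 10121 bp covered in control to 7937 bp in cKO (chromosome 17, 15367354 to 15376932). Ssbp4 had the largest decrease (11923 to 8776 bp), followed by Lgi4 (12169 to 9356 bp), Fam102a, Tprn, Dll1, the kinase gene Akt1 (9000 to 6866 bp), Cstad, the myelin glycoprotein gene Omg (5510 to 3421 bp), Tekt4 and the ephrin gene Efna2 (5825 to 3802 bp). Sgsh, which encodes a lysosomal sulfatase, had the largest increase (2219 to 5028 bp). It was followed by the phosphatase gene Ppp5c (1648 to 3202 bp), Flrt1, Slc25a18, the homeobox gene Meox1 (1308 to 2675 bp), Cotl1, Ccdc188, Zfp385c, the Wnt antagonist gene Frzb (listed at 0 in control, 1197 bp in cKO) and Lrtm2. None of these 20 genes was on chromosome X.

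The lists of bipolar interneuron and blood vessel genes had a lower mean H3K27ac coverage in the cKO library. They were the 2 of 25 lists outside the middle 95% for this mark, where 1.25 would be expected by chance. Of 14 bipolar genes with the mark, 11 had fewer covered bases and 3 had more, with a mean change of -233 bp over the 21 listed genes (0.77th percentile of 10000 random lists of matched coverage). The bipolar list lay inside the middle 95% without Bhlhe22 (4.59th percentile) or without Gpr179 (2.55th), and at the 9.93rd percentile with whole gene bodies and 5 kb either side. Bhlhe22 had 5174 bp in control and 3709 bp in cKO, Gpr179 went from 4650 to 3561 bp and Irx5 from 9925 to 9104 bp. Lhx4 (263 bp in control) and Cacna1s (333 bp) had no peak listed in cKO. The vascular endothelium and pericyte list had a mean change of -217 bp over 19 genes (0.03rd percentile, and at most the 0.84th without any single gene). Of its 9 marked genes 6 were lower and 3 higher, and the median change over the list was 0 bp. Among those lower, the vascular growth factor receptor gene Kdr went from 5924 to 4361 bp and the tight junction gene Cldn5 from 3650 to 2821 bp. The cadherin gene Cdh5 went from 1236 to 661 bp. Egfl7 went from 2179 to 867 bp, with a peak within 1 kb of an end in control alone. Among those higher, Flt1 was listed at 0 in control and 125 bp in cKO. Vessel cells are a cell type that dissected retina holds beside its neurons, and this list was the lowest in percentile of the 25 for H3K27ac. The cKO tissue came from peripheral retina chosen by its fluorescence. Position in the retina and cell proportions were not tested, and cannot be told apart from genotype here. The microglia and macrophage list lay at the 50.7th percentile and the retinal astrocyte list at the 15.6th.

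Retinal progenitor, Müller glia and amacrine genes had mostly lower H3K27ac as well, inside the range of random lists of matched coverage. H3K27ac coverage was lower in cKO on every chromosome used, by -5.69% on X and from -8.80% to -5.78% over the 19 autosomes. Counts of genes lower are therefore not particular to these lists. The progenitor list had 20 of 23 marked genes lower (mean -396 bp, 4.96th percentile), among them Pax6 (12074 to 10859 bp), Ccnd1 (14720 to 13648 bp) and Fgf15 (7742 to 6487 bp). In the Müller glia list 24 of 29 marked genes were lower (mean -358 bp, 3.21st percentile), with Dkk3 at 11661 and 9789 bp and Kcnj10, an inward rectifier potassium channel gene, at 5671 and 4381 bp. The amacrine list had 16 of 19 lower (mean -291 bp, 3.17th percentile), with Prdm13 at 5388 and 4121 bp. Progenitor and Müller glia lists share 9 genes, and without these both lay below the middle 95% of random lists, at the 2.28th percentile (-493 bp) and the 0.96th (-410 bp). The call depends on the setting: without matching the progenitor (0.01st), Müller glia (0th) and amacrine lists (0.06th) lay below the range, as did the Müller glia (2.46th) and amacrine lists (1.225th) in 4 kb windows and the amacrine list (1.96th) at equal list length. The rod list had 10 of 17 marked genes lower and 7 higher (mean -102 bp, 39.4th percentile), with Nr2e3, a rod transcription factor gene, at 2060 and 2928 bp. Peaks within 1 kb of either gene end appeared in cKO alone at Ikzf1, an early temporal identity factor gene (253 to 519 bp), and Sox1 (listed at 0, then 791 bp). The same held for Gata2, Onecut3, Prdm1, Tbr1, Pde6c, Flt1 and S100b. In control alone they appeared at Reep6, C1qb, Csf1r and Gja1, beside Lhx4, Cacna1s and Egfl7. Covered bases in the wider windows went against this call at Prdm1 (768 to 594 bp), Tbr1 (2148 to 1950 bp) and Csf1r (158 to 191 bp). At the other genes named they went with it.

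Across 21631 protein-coding genes, 13285 in control and 13274 in cKO had an H3K27ac peak within 1 kb of either end. Of these, 307 had it in control alone and 296 in cKO alone. The mean change over the 15224 genes with any H3K27ac in the windows was -102 bp. Of control peaks, 31.1% (95% exact binomial interval 30.7 to 31.4, counting error only) met no cKO peak, and of cKO peaks 30.9% (30.6 to 31.2) met no control peak. Unshared peaks had median widths of 192 bp and 165 bp, beside 681 bp and 549 bp for shared ones. With 1 library per genotype, none of the differences in either histone mark has a replicate check, and none is tested.

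**Figure D2:**
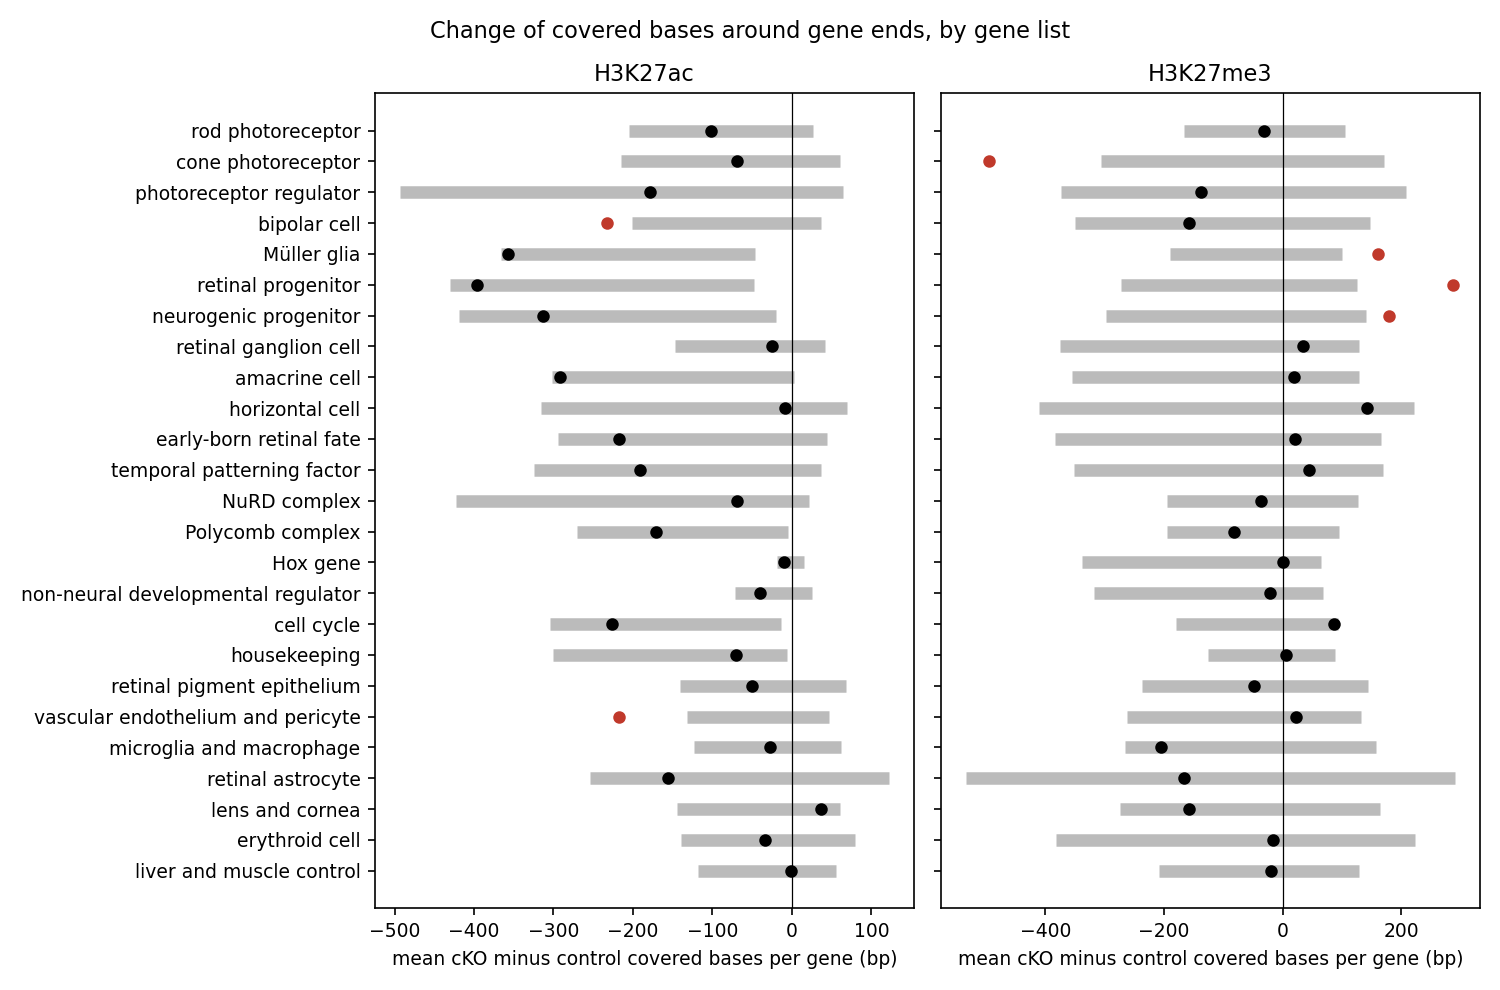
Each point is the mean cKO minus control difference in bases covered by peaks (bp per gene) around the ends of the genes of a list, for H3K27ac on the left and H3K27me3 on the right; grey bars span the middle 95% of 10000 random lists of the same size and matched coverage. Points in red lie outside their bar, which holds for 6 of the 50 combinations, where 2.5 would be expected by chance.

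The third comparison asked where H3K27me3 differed in cKO retina. Genes of multipotent retinal progenitors carried more of this repressive mark in the cKO library. Of 18 progenitor genes with H3K27me3, 15 had more covered bases and 3 had fewer, with a mean change of 288 bp over the 24 listed genes (99.99th percentile of random lists of matched coverage). Hes1, a transcriptional repressor downstream of Notch, went from 4897 to 6294 bp (chromosome 16, 30065357 to 30067796). There a cKO peak (30060913 to 30063258) spanned the gap between control peaks (30060697 to 30061723 and 30062144 to 30062943). The other H3K27me3 peaks at Hes1 lay at nearly the same places in both libraries, with shifted edges. H3K27ac peaks at Hes1 covered more bases in cKO as well. The eye field gene Pax6 went from 6210 to 7341 bp, Hmga2 from 6887 to 7841 bp, Sox9 from 5721 to 6649 bp, Notch1 from 2423 to 3260 bp and Rax from 1626 to 2456 bp. Sfrp2, the gene of a secreted Wnt modulator, had a peak within 1 kb of an end in cKO alone (425 to 1105 bp in the windows). Lhx2 (8868 to 8230 bp), Hes5 (448 bp, then listed at 0) and Cdk4 (2745 to 2410 bp) went the other way.

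Müller glia and neurogenic progenitor genes had more H3K27me3 too. The Müller glia list had a mean change of 161 bp over 30 genes (99.8th percentile), with 10 of 17 marked genes higher, led by Kcnj10 (1118 to 2764 bp). Without the 9 genes it shares with the progenitor list, Hes1, Sox9, Notch1 and Rax among them, its mean was 75.7 bp (91.6th percentile) and that of the progenitor list 246 bp (99.4th). The neurogenic list had a mean change of 180 bp over 20 genes (99.0th percentile), with 7 of 13 marked genes higher and 4 lower, and lay inside the range with gene bodies (95.33rd percentile). Insm1 went from 6900 to 8124 bp, and the proneural gene Neurog2 from 9756 to 10525 bp. Leaving out any single gene kept the progenitor list at or above the 99.88th percentile and the Müller list at or above the 98.09th, while the neurogenic list reached down to the 96.2nd. Members were picked here for their size of change after the values were seen, except those named for a peak within 1 kb of an end.

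**Figure D3:**
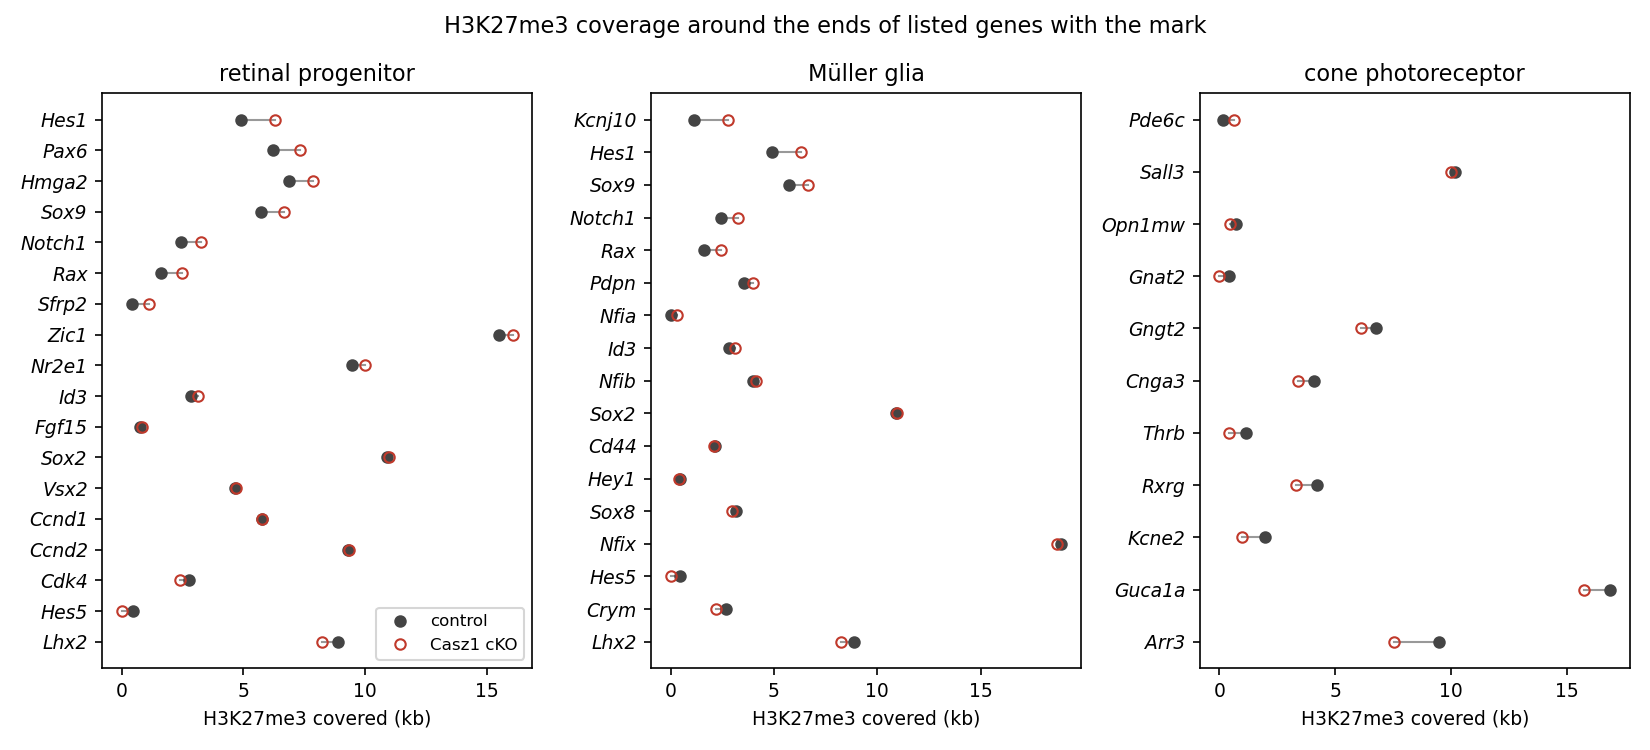
Bases covered by H3K27me3 peaks (kb) around the ends of each listed gene with the mark, in the control library (filled) and the Casz1 cKO library (open red), for the retinal progenitor, Müller glia and cone photoreceptor lists. Of the progenitor genes 15 of 18 lie to the right of control, and of the cone genes 10 of 11 lie to the left.

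Cone photoreceptor genes carried less H3K27me3 in the cKO library. Of 11 cone genes with the mark, 10 had fewer covered bases, and the mean change over 15 genes was -495 bp (0.13th percentile). Arr3, the cone arrestin gene on chromosome X, went from 9468 to 7540 bp, Guca1a, a guanylate cyclase activator gene, from 16884 to 15770 bp, and Kcne2 from 1989 to 956 bp. The nuclear receptor genes Rxrg (4227 to 3325 bp) and Thrb (1171 to 399 bp) and the channel gene Cnga3 (4081 to 3399 bp) were lower as well. On autosomes alone the cone mean was -404 bp (0.165th percentile), and with whole gene bodies and 5 kb either side it was -475 bp at the 8.85th percentile, inside the range of random lists. A list of dorsal retina genes, drawn up after Tbx2 was seen, lay without Tbx2 at the 86.06th percentile for H3K27me3 and the 1.56th for H3K27ac in the same libraries. The rod list had a mean change of -31.1 bp (45.8th percentile). Peaks within 1 kb of an end were found in control alone at Nrl, the rod determinant (2450 to 1610 bp in the windows), Rcvrn and Cngb1. At Cnga1 and Pde6a they were found in cKO alone. In the windows Cnga1 went from 2582 to 2639 bp, but Pde6a from 375 to 196 bp.

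**Figure D4:**
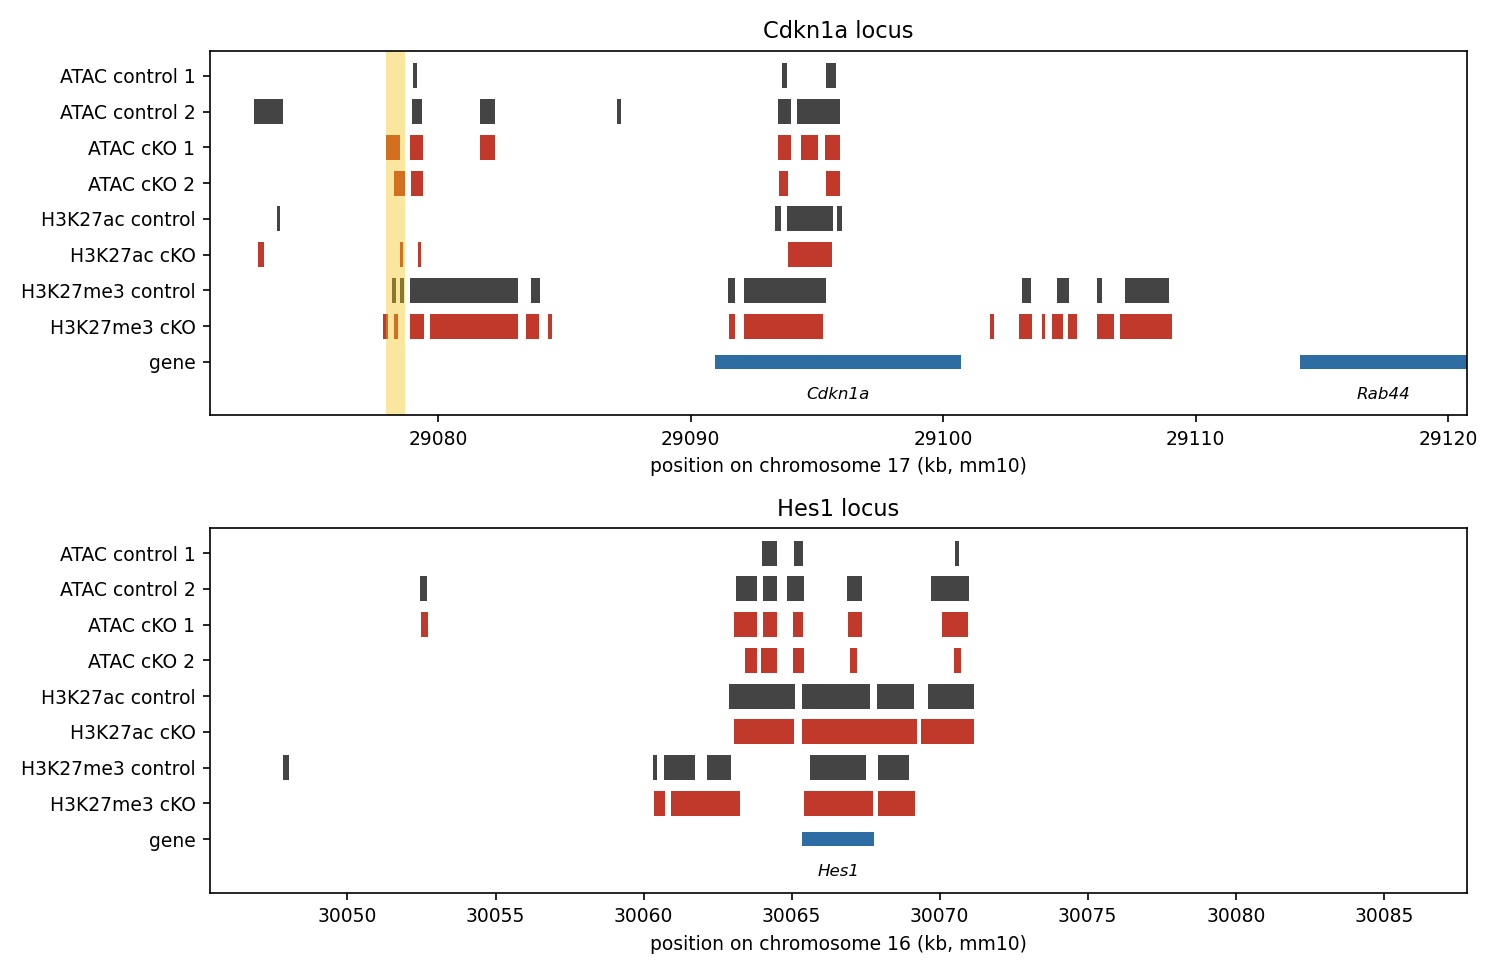
Called peaks in each library (grey, control; red, Casz1 cKO) and gene bodies (blue) over the Cdkn1a and Hes1 loci, by position in kb on mm10. The yellow band at Cdkn1a spans 29077958 to 29078681, where ATAC peaks were called in both cKO lists and in neither control list, and at Hes1 the H3K27me3 peaks cover 4897 bp of the windows in control and 6294 bp in cKO.

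By single genes, many of the largest increases and decreases of H3K27me3 lay on chromosome X. Of the 10 genes with the largest decrease, 8 were on X: Rbm41 (12116 to 7541 bp), Pir (12663 to 8644 bp), Gdpd2, Bmx, Dcx (10228 to 6833 bp), which encodes a microtubule protein of migrating neurons, Gspt2, Capn6 and Amot; the others were Krt28 (5876 to 1730 bp) and Atp6v1b1. Of the 10 with the largest increase, 5 were on X: Usp9x (6073 to 8900 bp), Gm15262, Pwwp3b, Nox1 and Dmrtc1c1. Tbx2, a dorsal eye transcription factor gene, stood second (8611 to 11065 bp; chromosome 11, 85832615 to 85841948), and Prss29, Olfr1415, Gm4861 and Gm6958 completed the group. Over the 427 X genes with the mark the mean change was -523 bp, and over autosomal genes -47.8 bp. The same cKO library held 35 H3K27me3 peaks on chromosome Y, beside 14 in control.

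The 4 Hox clusters were saturated with H3K27me3 in both genotypes. The mark covered 100% of the Hoxa, Hoxc and Hoxd clusters in both libraries, and 99.9% in control and 100% in cKO of the Hoxb cluster. H3K27ac peaks were listed in none of the clusters except a peak of 196 bp at Hoxa in control. The 39 Hox genes had a mean H3K27me3 change of 0 bp, and the 40 non-neural developmental regulators one of -21.1 bp (84.9th percentile).

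Within 1 kb of either end, 6407 genes in control and 6292 in cKO had an H3K27me3 peak; 546 had it in control alone and 431 in cKO alone. Listed genes with such a peak in cKO alone included the Polycomb genes Jarid2, Pcgf2 and Pcgf3, Sebox, Opn1mw, Gap43, B2m and Fgb. Those in control alone included Aebp2, Tpm3 and Pdgfrb. Covered bases in the wider windows were nevertheless fewer in cKO at Opn1mw (731 to 477 bp), Gap43 (322 to 138 bp) and Fgb (1123 to 846 bp). At the others named here they went with the call within 1 kb. The mean change over the 10591 genes with any H3K27me3 was -66.9 bp. Of control peaks, 35.2% (34.9 to 35.5) met no cKO peak, and of cKO peaks 30.9% (30.6 to 31.3) met no control peak. A full switch between marks within 1 kb of either end was rare: 6 genes (Sun5, Padi1, Nme9, H2-M3, Pcdhb11 and Pcdhb21) went from H3K27me3 alone to H3K27ac alone, and 6, among them Olfm3, Gm44805, Apoc2, D130037M23Rik and Ciita, went the opposite way. Peaks of the 2 marks need not lie at the same end of a gene. Gm44805 and Apoc2 share a gene end and all values, so they stand for the same place. At Ciita, H3K27me3 in the wider windows went from 1020 to 587 bp. 

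The lists not described so far lay within the middle 95% of random lists for both marks, given here as percentiles for H3K27ac and then H3K27me3. Among retinal lists, photoreceptor regulators lay at 56.3 and 28.5, ganglion cells at 70.8 and 88.0, horizontal cells at 87.2 and 92.3, early-born fates at 12.8 and 79.8, and temporal patterning factors at 27.4 and 82.0. Chromatin and cell biology lists gave 86.3 and 43.7 for NuRD, 28.0 and 28.9 for Polycomb, 16.6 and 97.0 for the cell cycle, and 84.8 and 65.1 for housekeeping genes. Pigment epithelium lay at 37.2 and 42.1, microglia and macrophages at 50.7 and 6.38, astrocytes at 15.6 and 32.5, lens and cornea at 93.05 and 15.7, erythroid cells at 44.7 and 62.0, and liver and muscle at 74.6 and 55.0. Cone genes lay at 51.3 for H3K27ac, neurogenic progenitors at 15.3, Hox genes at 14.0 and non-neural regulators at 21.7, and for H3K27me3 bipolar genes lay at 27.6, amacrine genes at 84.9, vascular genes at 78.0 and Hox genes at 89.5.

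The last comparison set the ATAC regions against the histone marks, which came from separate tissue at another age. Of the regions open in all 4 ATAC lists, 67.3% (66.8 to 67.8) met H3K27ac in both genotypes. Of the 325 cKO-only regions, 65 (15.8 to 24.8%) met H3K27ac in both genotypes, 5.54% (3.32 to 8.61) in control alone and 5.85% (3.56 to 8.98) in cKO alone. Of the control-only regions, 20.5% (14.3 to 28.0) met it in both, 3.42% (1.12 to 7.81) in control alone and 2.05% (0.426 to 5.89) in cKO alone. The control-alone and cKO-alone shares are parts of the same regions, and each mark has 1 library per genotype. Their difference was therefore not tested, and the intervals cover counting error only. Regions called in control replicate 2 and cKO replicate 1 only do not follow genotype. They met H3K27ac in both at 18.7%, in control alone at 5.39% and in cKO alone at 5.28%. The region near Cdkn1a was among those with an H3K27ac peak in cKO alone, at 29078494 to 29078604. The narrowest peak of that list was 111 bp wide, and this peak was no wider. The region near Cdkn1a also held H3K27me3 peaks in both libraries.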

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

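Of the tests of explanations in this part, that on H3K27ac peaks of chromosome Y was chosen after its values were seen, and that with wide peaks after the pattern on X was seen. Chromosome Y, which no comparison used, carried 35 H3K27me3 peaks in the cKO library (exact Poisson interval 24.4 to 48.7) and 14 in control (7.65 to 23.5), so that the cKO count lay above the control by more than both counting intervals. The 4 ATAC lists had from 26 to 47. On chromosome X, H3K27me3 covered 14.4 Mb in cKO and 15.9 Mb in control.

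Coverage on X was lower by more than on any autosome. Covered bases of H3K27me3 on X changed by -9.42%, beside -3.05% to 0.538% over the 19 autosomes, and 298 of 427 marked X genes had fewer covered bases. Fewer narrow peaks called in the cKO library are argued against, since with peaks of at least 300 bp the change on X was -10.5%, beside -3.65% to 0.832% over the autosomes. A larger share of male tissue in the cKO sample may account for both chromosomes, because the inactive X of females is coated with H3K27me3, yet H3K27ac had 42 Y peaks in cKO and 32 in control, with overlapping intervals, which leaves it open. The labels give no sex and there is 1 library per genotype, so it cannot be told apart from an effect of Casz1 loss on the X.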

How the results depend on the processing

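Of the alternatives, equal list length by width, peaks of at least 300 bp, gene bodies, crossed numbers, and for the lists 4 kb windows, autosomes and removal of shared members were chosen after the data were seen. Compared with the reported values, 79 alternatives stayed within the spread, the counting interval or 1.5 times, 42 moved, 4 weakened and 1 changed sign. Depth is unknown, so how far it limits each list was not tested, and where no construction is named the cause was not tested.

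The 146 control-only ATAC regions became 83 with 50% covered, 538 at equal list length and 3 with peaks of at least 300 bp; the 325 cKO-only regions became 771 and 41 under the latter 2. Leaving out each library gave 388 to 22948 control-only and 368 to 18030 cKO-only regions, which then rest on fewer lists, and a Jaccard difference of -0.271 to -0.0153. The replicate block gave a difference of 0.00716 and left 146 and 325 by construction. Crossed numbers, chosen for their correlation, gave -0.342 and the same 146 and 325 regions.

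Unshared H3K27ac peaks made up 42.2% of control and 38.5% of cKO peaks with 50% covered, 27.9% and 29.8% with peaks within 500 bp merged, 32.4% and 27.3% at equal length, and 21.6% and 13.5% at 300 bp or more. For H3K27me3 the same settings gave 49.9% and 44.6%, 38.0% and 33.1%, 34.0% and 31.6%, and 27.7% and 22.0%, with 36.5% and 33.6% on autosomes. Genes with an H3K27ac peak within 1 kb of either end in cKO alone numbered 167 at 300 bp or more. The mean change over gene bodies was -197 bp for H3K27ac and -157 bp for H3K27me3, and -28.1 bp for H3K27me3 in 4 kb windows.

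Combinations of list and mark outside the middle 95%, 6 of 50 as reported, numbered 11 without matching, 11 with 4 kb windows and 3 with gene bodies. Those that came in without matching were H3K27ac over the Müller glia, progenitor, neurogenic, amacrine and cell cycle lists; with 4 kb windows they were H3K27ac over the rod, Müller glia, amacrine and non-neural regulator lists and H3K27me3 over the microglia list. With gene bodies the cone (-475 bp), bipolar (-341 bp) and neurogenic lists (180 bp) lay inside the range, as did the Müller glia list without shared members (75.7 bp); each kept its sign. Overlap of cKO-only regions with cKO H3K27ac was 17.8% with 50% covered, and within 10 kb listed genes had 1 control-only and 2 cKO-only regions. Thresholds on q, equal length by p, transcript 5' ends and motifs were not run.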

Other observations

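The dorsal, ventral, p53 and interferon lists and the tests of explanations in this part were chosen after the values were seen. Tbx2, Tbx3 and Vax2, transcription factor genes that pattern the eye from dorsal to ventral, differed between the H3K27 libraries in opposite directions. At the dorsal gene Tbx2, H3K27me3 went from 8611 bp in control to 11065 bp in cKO and H3K27ac from 18716 to 17568 bp. Tbx3 went from 9352 to 7850 bp of H3K27ac. At the ventral gene Vax2, H3K27me3 went from 13155 to 11418 bp and H3K27ac from 5293 to 5946 bp. The dorsal list holds Tbx2, which prompted it. Its mean change was -506 bp for H3K27ac and 410 bp for H3K27me3 with Tbx2, and without it -414 bp (1.56th percentile) and 118 bp (86.06th), the latter inside the range of random lists, while Bmp4, a dorsal signal, went the other way for H3K27me3 (16183 to 14683 bp). The ventral list lay at the 86.3rd percentile for H3K27ac and the 13.1st for H3K27me3.

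Genes of the p53 response were examined because Cdkn1a headed the cKO-only ATAC regions. Of the 24 listed genes, Cdkn1a and Mdm2 (7.07 kb) had a cKO-only region nearest to them. The list was drawn up because of the first of these, so its rank among random lists is not read. The region at Mdm2 had peaks of 189 and 345 bp. Of the interferon list, Ifi205 had a cKO-only region (95.9th percentile), and of the ventral list Aldh1a3 (86.5th). The covered bases of the p53 list changed by a mean of -95.7 bp for H3K27ac (40.2nd percentile) and 98.1 bp for H3K27me3 (95.7th), and those of the interferon list by -119 bp (8.79th) and -38 bp (46.8th).

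The 325 and 146 ATAC regions called by genotype were also examined after their counts were seen. Over the regions that differed in both crossed pairs, the odds ratio for the same direction in each was 1.503, with a jackknife interval over 20 chromosomes of 0.884 to 2.56. The interval spans equal odds, and most of these regions were among the narrow peaks of their lists, with median lower percentiles of 8.95 and 6.94.

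The ATAC lists grouped by crossed replicate numbers. Exchanged genotype labels after peak calling are argued against by the names of the peaks, which carried the labelled genotype in all 4 lists. Shorter lists of peaks at the same places may account for part of it, since at least 95.1% of the peaks of control replicate 1 and of cKO replicate 2 overlapped each of the longer lists. Whether list length is the whole cause was not decided. With lists of equal length by width the Jaccard difference stayed at -0.147 (-0.167 as reported), and the crossed pairs alone shared 3796 and 6329 regions, beside 538 and 771 by genotype. That setting keeps the widest peaks and leaves covered bases unequal. Median widths were 210 bp in control replicate 1 and 239 bp in cKO replicate 2, beside 474 bp in control replicate 2 and 485 bp in cKO replicate 1. Narrower peaks, depth, cell quality and the day of the experiment stay open, untested.

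H3K27me3 covered more of the progenitor and Müller glia genes and less of the cone genes in the cKO library. The Müller glia list lay inside the range of random lists without the members shared with the progenitor list (91.6th percentile). So did the cone list with gene bodies (8.85th). The marked genes as a whole did not gain coverage in cKO, with a mean change of -66.9 bp (median -37 bp) and -47.8 bp on autosomes. Genes went both ways (SD 515 bp), so this mean cannot decide whether peak calling in cKO was more sensitive at some genes. Fewer narrow peaks in cKO are argued against for the cone list, which lay at the 1.48th percentile (-371 bp) with peaks of at least 300 bp and at the 0.11th (-487 bp) at equal list length, while trimmed edges of wide peaks were not tested. Fewer dorsal cells in the dissected cKO tissue cannot be told apart from the genotype: without Tbx2 the dorsal list lay at the 86.06th percentile for H3K27me3 and the 1.56th for H3K27ac, and 1 library per genotype leaves position and genotype confounded. The choice of peripheral cKO tissue and the proportions of cell types were not tested, and are confounded in the same way. An effect of Casz1 loss on Polycomb marking of these genes stays open, as a hypothesis found in the same pair of libraries and untested in others.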
